A study of Rattus norvegicus with 24 samples.

How the data were processed

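Liver RNA from 24 Sprague-Dawley rats, an outbred laboratory stock, was measured by bulk RNA sequencing, with 1 library per animal and no pooling. The labels placed 6 animals in each of 4 groups: sham-exposed females, PCB 52-exposed females, sham-exposed males and PCB 52-exposed males. Replicates were numbered in accession order within a group, so these numbers name libraries and pair none of them. Animal numbers were taken from the sample titles.

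Per the labels, the values were gene counts in 1 table for each sex, deposited by the authors without normalization. Reads were checked with FastQC and aligned with HISAT2 to the rat genome build rn6, per the submitters' processing notes. The counting tool, the strand setting and the annotation were not given in the sources used here, and the extract protocol in the labels names both poly(A) capture and rRNA removal. Reads from overlapping or antisense genes therefore could not be told apart, and near-identical family members such as Cyp2b1 and Cyp2b2 were treated as uncertain. Both tables held the same 15319 Entrez gene IDs, of which 15230 matched a symbol in a RefSeq gene table of the GRCr8 assembly. The 89 IDs without a symbol took at most 2.30% of a library's counts and stayed in the library totals and tests. The assembly differed from the authors' build, so no coordinates are given. No mitochondrially encoded gene was among the measured genes (0 found).

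Library totals ran from 6994832 to 9185511 counts, and 1 count was worth 0.143 CPM (counts per 1e+06 library counts) in the smallest library and 0.109 CPM in the largest. Between 12011 and 12434 genes had counts in a library, and 1253 genes had none in any library. Counts of replicate pairs differed by more than sampling noise, with the lowest chi-square per degree of freedom at 7.01, so no library was treated as a duplicate. Intervals and floors cover counting error only where they are said to come from counts, since no molecular identifiers were used here.

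Differential expression was tested with edgeR 4.0.16 in R 4.3.3. The settings were TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and the robust quasi-likelihood test. Adjusted p-values are from Benjamini-Hochberg adjustment, with a threshold of 0.05. Each sex was fitted within its own table. The difference between the sexes in the response, the average of both responses and the contrast of sham females with sham males came from 1 fit of all 24 libraries. These choices, the gene lists and the rule for named genes were made before the data were examined. Fold changes are given as log2 values with their standard errors (SE), and CPM as mean ± SD.

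In total 38 gene lists were fixed for liver functions, xenobiotic receptors and the cell types of liver. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided and adjusted over the lists tested. Camera compares a list with all other genes. The same test with the correlation estimated for each list was an alternative, as was fry. Fry tests whether the genes of a list move, on balance, in a single direction, without comparing them with other genes.

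The named genes followed a fixed rule. Where fewer than 10 genes passed, the 5 higher and 5 lower genes with the smallest p were named and said not to pass. The 10 preset genes of PCB and thyroid hormone responses were named in every comparison of exposure, along with preset sex-specific genes for the sham contrast and up to 4 members of each list described. Genes with provisional symbols were left out of the naming, and Kdm5d, preset for the sham contrast, was not analysed here. A gene that the rule selects in the sham contrast is not reported here. Single genes named outside the rule are said to be chosen after their values were seen.

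Other settings fixed beforehand were median-of-ratios (RLE) factors, no low-count filter, a filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fit that was not robust, 1 surrogate variable from sva 3.50.0, all 24 libraries in 1 fit, each library left out in turn and an adjusted p threshold of 0.10. A library axis, described with the results, was found after seeing the data. It is the leading principal component of log2 CPM within groups, scored in each sex with gene weights from the other sex. Alternatives chosen after seeing the data were this score as a covariate, a fit without animals 13 to 16 and a block for consecutively numbered animals.

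The tests were tried on simulated counts drawn from the means and library sizes of the real samples, with some genes changed. In females 66 genes were changed 1.5-fold, 71 were changed 2-fold and 63 were changed 3-fold, with similar numbers in the other comparisons. The cholesterol synthesis list was also raised 1.5-fold. Of genes changed 1.5-fold, 54.5% were recovered in females (10172 genes in the step), 72.4% in males (10087), 35.6% for the difference between the sexes (10474), 77.9% for the average (10476) and 50.0% for the sham contrast (10464). At a 2-fold change the shares were 90.1%, 84.8%, 70.1%, 98.3% and 82.4%, in the same order. False calls made up 5.85% of the calls in females, 5.15% in males, 3.65% for the difference, 5.21% for the average and 8.38% for the sham contrast. The simulated libraries carried no axis shared between animals. The shares recovered apply to that many changed genes and were not measured for fewer.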

Results

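The livers of 24 adolescent Sprague-Dawley rats were profiled by RNA sequencing, 6 in each of 4 groups: sham females, PCB 52 females, sham males and PCB 52 males. PCB 52 is a polychlorinated biphenyl (PCB), a member of a class of persistent industrial chemicals. Exposed animals breathed it through a nose-only apparatus for 4 hours a day over 28 days, at an airflow of 12 L/min. Exposure began at 42 days of age in females and 39 days in males. Libraries held between 6994832 and 9185511 gene counts. The design asks which liver genes differ after inhalation in each sex and whether the sexes respond differently, and each replicate was a separate animal.

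The libraries also varied along an axis that the labels do not name. It held 16.7% of the within-group variance in females and 19.8% in males. Csnk1g2, Ehmt2 and F12, the gene of a coagulation factor, lay at its low end, and Cast, Gpbp1 and Thoc2, the last a part of the mRNA export machinery, lay at its high end. Ribosomal protein genes ran against the score, with a median r of −0.504 across libraries. Sham scores ran from −7.12 to 6.98, and animals 13 to 16, all exposed, scored 9.32, 10.8, 8.31 and 12.7. Mean scores were 5.15 higher in exposed than in sham females (two-sided exact permutation p = 0.190, n = 6 per group) and 4.24 higher in exposed males (exact p = 0.219). Across the 12 pairs of consecutively numbered males and females, group-centred scores correlated with r = 0.916 (one-sided permutation p = 4.8e-04) and rho = 0.797 (permutation p = 0.00668). Without the 2 pairs farthest from the median score, r was 0.893. The labels give no pairing, so this is a pattern in the data and not part of the design.

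**Figure D1:**
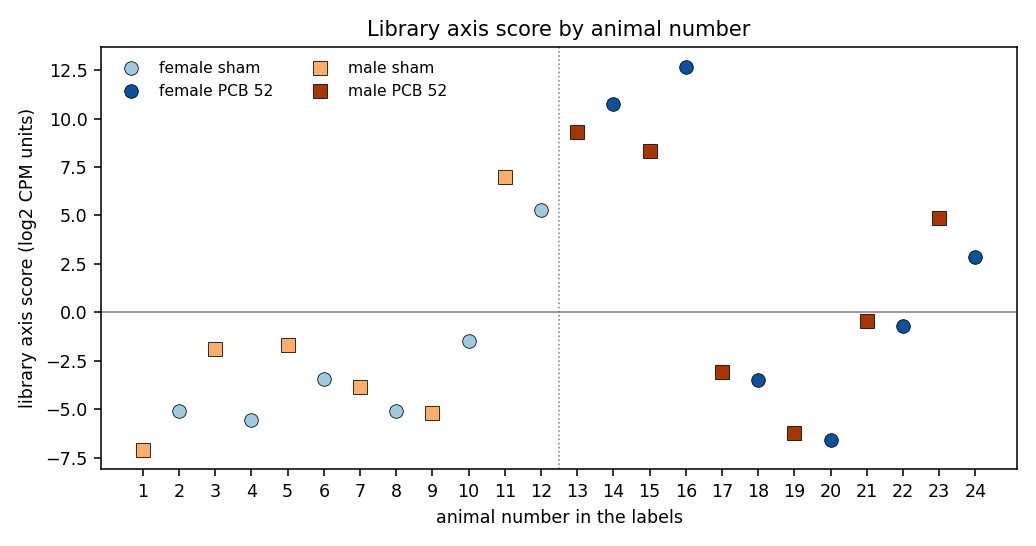
Library axis score (log2 CPM units) against animal number, 1 point per library, with circles for females and squares for males and a dotted line between sham and PCB 52 animals. Animals 13 to 16 score between 8.31 and 12.7, above the sham maximum of 6.98.

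In females, a lipogenic enzyme and a gluconeogenic enzyme were among the genes with the smallest p, in opposite directions. Acly, ATP citrate lyase, which makes cytosolic acetyl-CoA for fatty acid synthesis, averaged 932 ± 90.7 CPM in exposed and 584 ± 142 CPM in sham females (SD, n = 6). This was a log2 fold change of 0.67 ± 0.13 (SE), and 6 of 6 exposed libraries lay above the sham mean. Pck1, the rate-limiting enzyme of gluconeogenesis, averaged 2609.9 ± 579.7 CPM against 4105 ± 473 CPM in sham, a log2 fold change of −0.66 ± 0.13, with 6 of 6 exposed libraries below the sham mean. Neither gene passed, each with an adjusted p of 0.172.

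The other genes with the smallest p in females were of varied function. Nrbf2, which encodes a binding partner of nuclear receptors and an autophagy regulator, averaged 31.8 ± 4.52 CPM in exposed and 48.4 ± 6.55 CPM in sham females (log2 fold −0.60 ± 0.11, adjusted p = 0.172). Hes1, a transcriptional repressor downstream of Notch, had a log2 fold of −0.58 ± 0.11, Ppp1r10 one of −0.54 ± 0.11 and B4galnt1, a ganglioside synthase, one of −0.45 ± 0.09. On the higher side were Hltf, a chromatin remodeler (0.70 ± 0.17), Akr1c13, an aldo-keto reductase (0.52 ± 0.12), Afap1l2 (0.76 ± 0.18) and Cbln3 (0.37 ± 0.09). Each of these 10 genes had all 6 exposed libraries on the same side of the sham mean, which follows in part from choosing them by smallest p. Adjusted p ranged from 0.172 to 0.317.

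By the edgeR quasi-likelihood test, 0 of 10251 genes passed in females, with 1021 genes at an unadjusted p under 0.05 (476 higher, 545 lower) where chance alone gives 513. DESeq2 called 27 genes (7 higher, 20 lower) and limma-voom 1, Pck1. Without PCB 52 female replicate 4, 8 genes passed, all lower and among them Pck1 and Nrbf2. Without sham female replicate 5, 1 gene passed, Cyp17a1, a steroidogenic enzyme chosen after its values were seen.

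**Figure D2:**
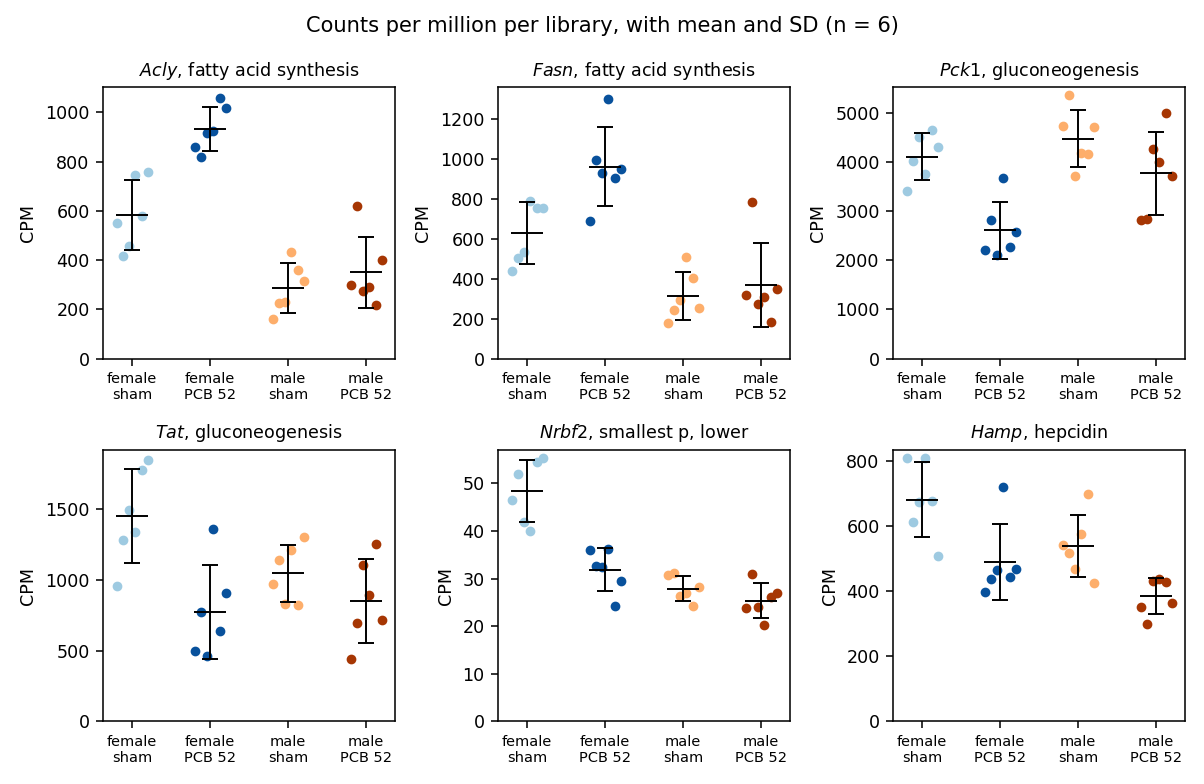
CPM per library for 6 genes in the 4 groups, with the mean and SD of 6 libraries as lines. Exposed females lie above all sham females for Acly (820.4 CPM or more against 756 CPM or less), while Pck1 averages 2609.9 CPM in exposed against 4105 CPM in sham females.

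Genes of fatty acid and triglyceride synthesis rose as a list in exposed females. Of 22 measured members, 20 had positive fold changes, with a median log2 fold of 0.39 (camera adjusted p = 3.74e-06, and adjusted p = 0.126 with an estimated correlation). Of these, 10 were higher when adjusted over the list alone, against 0 over all genes tested. They included Fasn, fatty acid synthase (0.61 ± 0.16), Pklr, the liver pyruvate kinase (0.44 ± 0.12), and Acacb, an acetyl-CoA carboxylase (0.56 ± 0.16).

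Genes of gluconeogenesis and fasting fell as a list, with 17 of 18 members below 0 and a median log2 fold of −0.27 (camera adjusted p = 2.45e-05, and adjusted p = 0.126 with an estimated correlation). Of these, 3 were lower when adjusted over the list alone, Pck1, Tat and G6pc1, against 0 over all genes. Tat, tyrosine aminotransferase, had a log2 fold of −0.91 ± 0.25 and G6pc1, the glucose-6-phosphatase catalytic subunit, one of −0.41 ± 0.12. Slc37a4, the glucose-6-phosphate transporter, had −0.24 ± 0.09.

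Glucocorticoid responsive genes fell as a list, with 13 of 15 members below 0 and a median log2 fold of −0.52 (camera adjusted p = 6.19e-06, and adjusted p = 0.0932 with an estimated correlation). The members lower when adjusted over the list alone were 9, and 1 was higher, against 0 over all genes. The metallothioneins Mt2A (−0.63 ± 0.15) and Mt1 (−0.35 ± 0.11), which also respond to metals, were among the lower ones, together with Tat. The higher member was Arrdc3 (1.16 ± 0.39), an arrestin-domain gene.

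Immediate early genes, which respond rapidly to signals reaching the cell, fell as a list, with 17 of 18 members below 0 and a median log2 fold of −0.39 (camera adjusted p = 6.19e-06, and adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 0 members passed by edgeR, as over all genes, and 7 had an unadjusted p under 0.05. Klf4 had a log2 fold of −0.94 ± 0.30, Gadd45b −0.71 ± 0.23, Zfp36 −0.31 ± 0.11 and Jund −0.41 ± 0.16.

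Among smaller shifts in females, ribosomal protein genes fell, with 32 of 33 members below 0 and a median of −0.13 (camera adjusted p = 4.35e-06). This list had an adjusted p of 0.505 with an estimated correlation, and it ran against the library axis as given above. Thyroid hormone responsive genes fell (10 of 13 below 0, median −0.20, adjusted p = 0.0209, and adjusted p = 0.126 with an estimated correlation). Their members lower when adjusted over the list alone were 4, Pck1, G6pc1, Bcl3 (−0.62 ± 0.21) and Klf9 (−0.36 ± 0.13), and 1 was higher, Me1 (0.61 ± 0.19), against 0 over all genes. PPAR alpha targets, genes of fatty acid oxidation, also fell (22 of 27 below 0, median −0.15, adjusted p = 0.0143, and adjusted p = 0.505 with an estimated correlation), with Plin2 at −0.42 ± 0.18.

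Markers of other cell types went in different directions in females. Stellate cell and collagen markers rose (14 of 18 above 0, median 0.19, camera adjusted p = 0.0143), led by Tagln at 0.68 ± 0.22, and cell cycle genes rose (14 of 17 above 0, median 0.25, adjusted p = 0.0419). Both had an adjusted p of 0.505 with an estimated correlation. Mcm7, the cell cycle member with the smallest p, went the other way (−0.42 ± 0.13). Periportal hepatocyte markers fell by camera (8 of 14 below 0, median −0.09, adjusted p = 0.0441). Pck1, also a member of that list, was its 1 member to pass when adjusted over the list alone. Erythroid markers fell (5 of 5 below 0, median −0.39, adjusted p = 0.0419). Both lists had an adjusted p of 0.505 under an estimated correlation. Adipocyte markers fell (5 of 5 below 0, median −0.31, adjusted p = 8.28e-04, and adjusted p = 0.103 with an estimated correlation), but 1 of those 5 was Pck1, the single member to pass when adjusted over the list alone. Kupffer cell and macrophage markers (median −0.04, adjusted p = 0.397) and acute phase genes (median −0.02, adjusted p = 0.791) did not pass.

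In total 12 of 33 tested lists passed in females by camera, 3 higher and 9 lower, against 0 with an estimated correlation and 6 by fry. By fry 2 lists passed with the library axis score as a covariate and 0 without animals 13 to 16, both settings chosen after seeing the data. Without sham female replicate 5, 6 lists passed. Among 100 random splits of the female libraries, the real one included, 3 passed at least 12 lists by camera. The other splits passed from 0 to 13 lists, and the first ones drawn passed 9, 6, 2, 7 and 6. Camera with the preset correlation thus passed lists for random groupings as well, so its adjusted p-values here overstate the evidence.

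**Figure D3:**
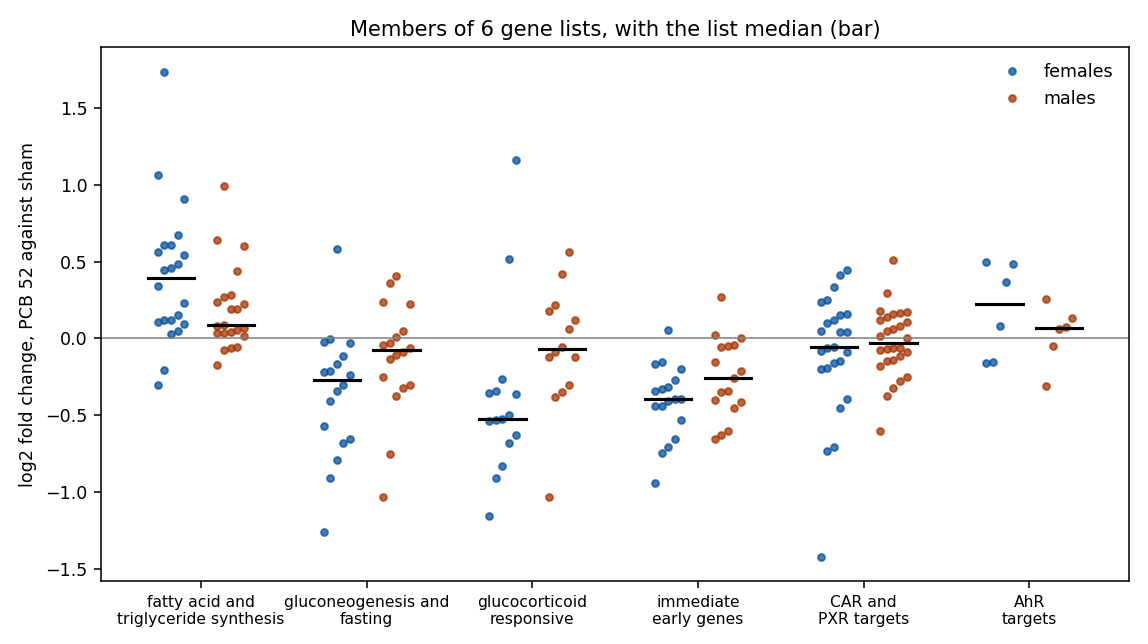
Log2 fold change of each measured member of 6 gene lists, PCB 52 against sham, with a bar at the list median, in females (blue) and males (dark orange). Medians in females are 0.39 for fatty acid and triglyceride synthesis, −0.27 for gluconeogenesis and fasting, −0.52 for glucocorticoid responsive and −0.39 for immediate early genes, while CAR and PXR targets centre on −0.06.

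The drug-metabolizing genes through which PCBs are known to act showed no difference that passed over all genes in either sex. CAR and PXR, the nuclear receptors for phenobarbital-like inducers, and AhR, the dioxin receptor, control these genes. In males Cyp2b1 had a log2 fold of −0.32 ± 0.45 and Cyp2b2 −0.38 ± 0.44 (101 ± 22.6 against 131 ± 90.0 CPM, SD, n = 6). These paralogs are nearly identical, so their split is uncertain. Both values rested on single libraries: Cyp2b1 ran from −0.61 (without PCB 52 replicate 3) to −0.02 (without sham replicate 6), and Cyp2b2 from −0.57 (without sham replicate 3) to −0.08 and −0.13 (without sham replicates 5 and 6). In females Cyp2b1 was below the filter (0.872 ± 0.346 CPM in sham, 1.57 ± 2.09 CPM in exposed) and Cyp2b2 stood at 0.45 ± 0.93. For Cyp2b2 only 1 of 6 exposed females, replicate 1, lay above the sham mean, and without it the log2 fold was −0.86. Cyp3a23-3a1 had intervals of −0.67 to 0.28 in females and −0.22 to 0.26 in males. Cyp1a1 had a log2 fold of −0.15 ± 0.36 in females and −0.31 ± 0.37 in males, and Cyp1a2 one of −0.16 ± 0.10 and −0.05 ± 0.16, with 95% intervals that include 0. With 1 library left out Cyp1a1 ran from −0.53 (without PCB 52 replicate 4) to 0.01 (without PCB 52 replicate 2) in females and from −0.54 (without PCB 52 replicate 3) to −0.08 (without sham replicate 4) in males. The range of Cyp1a2 in males was −0.19 (without PCB 52 replicate 3) to 0.03 (without PCB 52 replicate 2). Cyp3a23-3a1 ran from −0.37 (without PCB 52 replicate 2) to −0.04 (without sham replicate 1) in females and from −0.06 (without sham replicate 6) to 0.07 (without sham replicate 4) in males.

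Nqo1, a quinone reductase shared by the AhR and Nrf2 programs, had log2 folds of 0.37 ± 0.14 in females (adjusted p = 0.438) and 0.25 ± 0.13 in males (adjusted p = 0.829), with 12 of 12 exposed animals above the sham mean of their sex. Without PCB 52 female replicate 6 the female log2 fold of Nqo1 was 0.22. Gadd45b had −0.71 ± 0.23 (adjusted p = 0.395) and −0.61 ± 0.27 (adjusted p = 0.829). Ugt1a1, which glucuronidates thyroxine and bilirubin, Thrsp, a thyroid hormone responsive lipogenic gene, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had values of −0.09 ± 0.12, 0.12 ± 0.14 and −0.14 ± 0.35 in females. In males they stood at −0.06 ± 0.12, 0.19 ± 0.17 and −0.09 ± 0.30. Single libraries moved these values too: Cyp7a1 ran from −0.25 (without PCB 52 replicate 3) to 0.11 (without sham replicate 4) in males and from −0.41 (without PCB 52 replicate 4) to −0.01 (without sham replicate 5) in females. Ugt1a1 ran from −0.16 (without PCB 52 replicate 5) to 0.01 (without sham replicate 1) in males and from −0.15 (without sham replicate 4) to 0.01 (without sham replicate 6) in females. The range of Thrsp was 0.10 (without sham replicate 1) to 0.31 (without sham replicate 4) in males and 0.04 (without sham replicate 2) to 0.23 (without sham replicate 4) in females.

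As lists, CAR and PXR targets split 12 above and 13 below 0 in females (median −0.06, adjusted p = 0.211) and 14 and 14 in males (median −0.03, adjusted p = 0.949). Adjusted over the list alone, 5 members passed in females, against 0 over all genes. The transporter Abcc2 was higher (0.41 ± 0.11), and the efflux pump Abcb1b (−1.42 ± 0.32), Por, the electron donor of cytochromes P450 (−0.45 ± 0.15), Cyp3a18 (−0.74 ± 0.24) and Gadd45b were lower. AhR targets had adjusted p of 0.124 in females and 0.666 in males. Adjusted over the list alone, 2 of their 6 members passed in females, Ugt1a6 (0.48 ± 0.12) and Nqo1, both higher, against 0 over all genes.

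**Figure D4:**
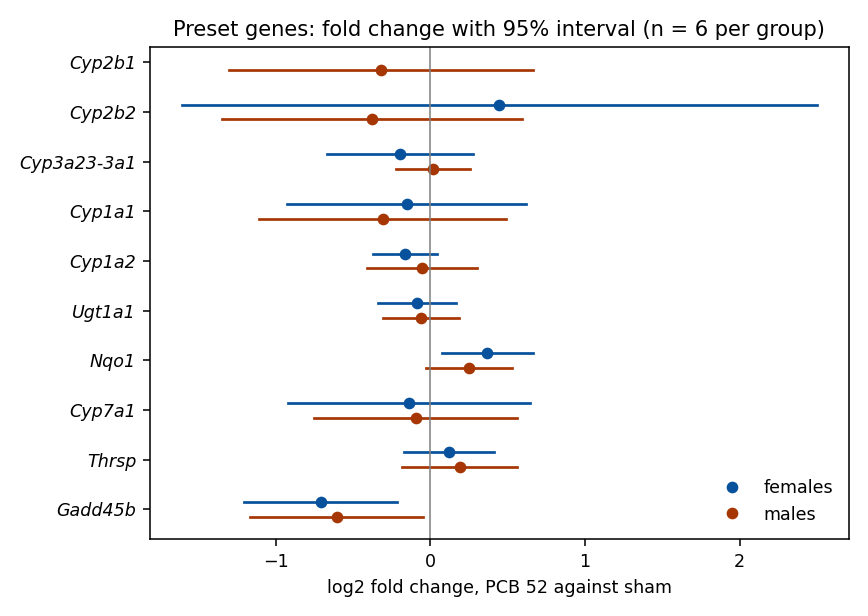
Log2 fold change, PCB 52 against sham, of 10 preset genes with 95% confidence intervals, for females (blue) and males (dark orange), 6 animals per group. The Cyp3a23-3a1 intervals run from −0.67 to 0.28 in females and from −0.22 to 0.26 in males, and Cyp2b1 in females was below the filter and has no point.

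In males, genes of varied function had the smallest p. Uso1, a vesicle tethering factor of the Golgi, averaged 194 ± 20.6 CPM in exposed and 158 ± 10.4 CPM in sham males (SD, n = 6), a log2 fold of 0.30 ± 0.08. Ssr3, a subunit of the translocon-associated complex, had 0.33 ± 0.09 and Bet1, a transport SNARE, 0.32 ± 0.09, followed by Gbe1, the glycogen branching enzyme (0.31 ± 0.08), and Maged1 (0.31 ± 0.09). On the lower side, Tssc4 averaged 11.5 ± 1.05 against 17.5 ± 2.44 CPM (−0.60 ± 0.11, adjusted p = 0.322). Hamp, which encodes the iron hormone hepcidin, averaged 385 ± 56.6 against 537 ± 95.2 CPM (−0.48 ± 0.12). Loxl1, a collagen crosslinking enzyme (−1.08 ± 0.24), the MHC class I gene RT1-A1 (−0.45 ± 0.11), uncertain for its near-identical relatives, and Zfp697 (−0.48 ± 0.12) followed.

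Each of these 10 genes had 6 of 6 exposed male libraries on its side of the sham mean, and none passed. That separation follows in part from choosing them by smallest p. The adjusted p was 0.829 for each gene but Tssc4. By edgeR 0 of 10180 genes passed in males, with 585 at an unadjusted p under 0.05 (295 higher, 290 lower) where chance gives 509. DESeq2 called 1 gene, Tssc4, and limma-voom 0.

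Immediate early genes fell as a list in males too, with 15 of 17 members below 0 and a median log2 fold of −0.26 (camera adjusted p = 0.00570, and adjusted p = 0.874 with an estimated correlation). Klf2 had −0.63 ± 0.27, Jund −0.40 ± 0.17, Gadd45b −0.61 ± 0.27 and Jun −0.46 ± 0.19. Ribosomal protein genes fell (25 of 33 below 0, median −0.06, adjusted p = 0.00570), as did PPAR alpha targets (20 of 26 below 0, median −0.08, adjusted p = 0.0308), with Acaa1b at −0.37 ± 0.17, and both had an adjusted p of 0.874 with an estimated correlation. Adjusted over the list alone, 0 members of these 3 lists passed by edgeR, as over all genes. By fry 0 passed. Among 100 random splits of the male libraries, the real one included, 65 passed at least 3 lists by camera. Without animals 13 to 16, a setting chosen after seeing the data, none of the 3 passed (adjusted p = 0.182 for immediate early genes, 0.858 for ribosomal proteins and 0.892 for PPAR alpha targets). Without PCB 52 male replicate 2, none of the 3 passed (adjusted p = 0.05001, 0.108 and 0.0698 in the same order) and 1 other list did, erythroid markers. Without PCB 52 male replicate 5, 6 lists passed, the 3 among them. Fatty acid and triglyceride synthesis (18 of 22 above 0, median 0.08, adjusted p = 0.249), gluconeogenesis and fasting (median −0.08, adjusted p = 0.189) and glucocorticoid responsive genes (median −0.07, adjusted p = 0.666) did not pass in males.

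The response of females minus that of males was then tested gene by gene and list by list. The genes with the smallest p were of low abundance. Ldhb, a lactate dehydrogenase subunit, averaged 2.89 ± 0.468 CPM in exposed and 1.96 ± 0.465 CPM in sham females but 1.44 ± 0.448 against 2.17 ± 0.467 CPM in males, a log2 difference of 1.14 ± 0.32. Etv5 (0.83 ± 0.23), Homez (0.76 ± 0.22), Tubgcp2 (0.38 ± 0.12) and Zfp697 (0.81 ± 0.26) also had positive differences. Camlg (−0.58 ± 0.16), Aig1 (−1.19 ± 0.35), C1h19orf47 (−0.60 ± 0.18), Mcm7 (−0.55 ± 0.17) and Dstyk (−0.54 ± 0.17) had negative ones. By edgeR 0 of 10535 genes passed, with 239 at an unadjusted p under 0.05 against 527 by chance and a smallest adjusted p of 1.00. DESeq2 and limma-voom also called 0.

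The 10 preset genes had 95% intervals for the difference that all include 0. The largest differences were those of Cyp2b1 (1.15 ± 0.88) and Cyp2b2 (0.83 ± 0.99), which went to 0.13 and −0.48 without PCB 52 female replicate 1. Cyp1a1 differed by 0.16 ± 0.57, Cyp1a2 by −0.11 ± 0.19, Cyp3a23-3a1 by −0.21 ± 0.26, Nqo1 by 0.12 ± 0.20, Gadd45b by −0.11 ± 0.39, Ugt1a1 by −0.03 ± 0.18, Thrsp by −0.07 ± 0.23 and Cyp7a1 by −0.04 ± 0.47. Single libraries moved the female or male values of several of these genes, as given above, which bears on these differences too.

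As lists, glucocorticoid responsive genes were lower in the female than in the male response (13 of 15 below 0, median difference −0.47, camera adjusted p = 3.19e-04, and adjusted p = 0.0927 with an estimated correlation). Mt2A differed by −0.85 ± 0.30, Mt1 by −0.47 ± 0.21 and Zbtb16 by −1.72 ± 0.78. Gluconeogenesis and fasting genes were also lower (13 of 18, median −0.19, adjusted p = 0.0222, and adjusted p = 0.529 with an estimated correlation), with Lpin1 at −1.50 ± 0.65 and Pck1 at −0.41 ± 0.19. Fatty acid and triglyceride synthesis genes were higher (18 of 22, median 0.26, adjusted p = 0.00485, and adjusted p = 0.529 with an estimated correlation), with Acacb at 0.53 ± 0.20.

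Cell cycle genes were higher in the female response (15 of 19, median 0.43, adjusted p = 7.71e-04, and adjusted p = 0.378 with an estimated correlation). Rrm2 differed by 1.54 ± 0.57 and Mki67 by 0.91 ± 0.40. Stellate cell and collagen markers were higher (15 of 18, median 0.18, adjusted p = 0.00147), with Tgfb1 at 0.55 ± 0.20, and had an adjusted p of 0.529 with an estimated correlation. Nrf2 targets (15 of 18, median 0.08) and cholesterol synthesis genes (19 of 24, median 0.16) were higher, each with an adjusted p of 0.0391, and 0.423 and 0.728 with an estimated correlation. Ribosomal protein genes were lower (28 of 33, median −0.09, adjusted p = 0.0231, and adjusted p = 0.728 with an estimated correlation). In these 8 lists 0 members passed when adjusted over the list alone, as over all genes by edgeR, and fry passed 0 of 33 lists. Among 100 random splits of the samples, the real one included, 14 passed at least 8 lists by camera. With the real groups but without sham male replicate 4, 4 lists passed. Without any of sham female replicate 2, sham male replicates 5 and 6, and PCB 52 male replicates 4 and 5, 5 did.

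Averaged over both sexes, Hamp, Apoa5, Akr1c13 and Uso1 were among the genes with the smallest p. Hamp had a log2 fold of −0.48 ± 0.10, with 11 of 12 exposed animals below the sham mean of their sex. Apoa5, an apolipoprotein that lowers plasma triglycerides, had −0.31 ± 0.06 (12 of 12 animals), averaging 1336 ± 168 against 1692 ± 219.9 CPM in females and 1139 ± 89.1 against 1373 ± 92.9 CPM in males (SD, n = 6). Akr1c13 stood at 0.40 ± 0.08 and Uso1 at 0.28 ± 0.06, each with 12 of 12 animals above the sham mean. Such counts of animals follow in part from the choice by smallest p. Nudt12, an NAD-capped RNA hydrolase (0.39 ± 0.08), Uggt1, a folding sensor for glycoproteins (0.34 ± 0.07), and Vwa5a (0.28 ± 0.06) were also higher in value, and Nrbf2 (−0.37 ± 0.08), Pck1 (−0.45 ± 0.10) and Tpst2, a tyrosylprotein sulfotransferase (−0.33 ± 0.07), were lower in value.

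Among the preset genes, Nqo1 averaged a log2 fold of 0.31 ± 0.10 (adjusted p = 0.169, 12 of 12 exposed animals above the sham mean of their sex) and Gadd45b −0.65 ± 0.19 (adjusted p = 0.146, 11 of 12 below). The other 8 had 95% intervals that include 0: Cyp2b1 (0.26 ± 0.44, and −0.25 without PCB 52 female replicate 1), Cyp2b2 (0.04 ± 0.49, and −0.61 without it), Cyp3a23-3a1 (−0.08 ± 0.13), Cyp1a1 (−0.23 ± 0.28), Cyp1a2 (−0.10 ± 0.09), Ugt1a1 (−0.07 ± 0.09), Thrsp (0.16 ± 0.11) and Cyp7a1 (−0.11 ± 0.24). For several of them single libraries moved the female or male value, as given above, so these averages are uncertain too.

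Of the 10 genes with the smallest p on average none passed, with adjusted p of 0.0855 or 0.0861. By edgeR 0 of 10535 genes passed on average, and 22 genes (13 higher, 9 lower) passed at an adjusted p of 0.10. At an unadjusted p under 0.05 there were 1625 (847 higher, 778 lower), where chance gives 527 for independent libraries. Consecutively numbered animals had a consensus correlation of 0.178 in limma. With them as a block, a setting chosen after seeing the data, limma gave 1284 such genes. The smallest adjusted p was then 0.213, so none passed at 0.10. DESeq2 called 99 genes (59 higher, 40 lower) and limma-voom with quality weights 7. Without PCB 52 female replicate 4, 15 genes passed. Without PCB 52 female replicate 3, 1 did (Akr1c13), and without sham female replicate 6, 2 did (Uggt1 and Hamp).

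On average over the sexes 8 of 33 lists passed by camera. Among 100 random splits, the real one included, 8 passed at least as many. Immediate early genes fell (16 of 18 below 0, median −0.35, adjusted p = 4.83e-05, and adjusted p = 0.189 with an estimated correlation), with 7 lower when adjusted over the list alone against 0 over all genes, led by Gadd45b (−0.65 ± 0.19), Jund (−0.40 ± 0.13) and Klf2 (−0.51 ± 0.18). Gluconeogenesis and fasting (median −0.15, adjusted p = 3.15e-04), glucocorticoid responsive (median −0.24, adjusted p = 0.00499) and adipocyte genes (6 of 6 below 0, median −0.28, adjusted p = 0.00499) fell. These 3 lists also had an adjusted p of 0.189 with an estimated correlation. Igfbp1, an insulin-repressed secreted protein gene (−0.72 ± 0.24), and Tat (−0.60 ± 0.18) were among 3 fasting genes lower when adjusted over the list alone, against 0 over all genes.

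Fatty acid and triglyceride synthesis rose on average (19 of 22 above 0, median 0.25, adjusted p = 2.19e-04, and adjusted p = 0.288 with an estimated correlation). Adjusted over the list alone, 6 were higher, among them Pklr (0.32 ± 0.09) and Scd, stearoyl-CoA desaturase (0.84 ± 0.25), and 1 was lower, Dgat1 (−0.19 ± 0.07), against 0 over all genes. Ribosomal proteins (30 of 33 below 0, median −0.12, adjusted p = 7.87e-07), PPAR alpha targets (22 of 27, median −0.11, adjusted p = 0.00193) and erythroid markers (5 of 5, median −0.31, adjusted p = 0.0201) fell, each with an adjusted p of 0.590 with an estimated correlation. By fry 5 lists passed, of which 4 were shared with camera, and 0 did with the axis score as a covariate or without animals 13 to 16.

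Female and male fold changes were positively related across 10035 genes (r = 0.380, rho = 0.428). Genes are not independent replicates, so no p is given for this. At an unadjusted p under 0.05 in both sexes, 61 genes were higher in both and 60 lower in both. The sexes share the library axis, so no expected count is given. With the library axis score as a covariate, a setting chosen after seeing the data, r was 0.217, and without animals 13 to 16 it was 0.193.

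Sham females and sham males differed in the known sex-specific genes of rat liver. Cyp2c11, the main male-specific cytochrome P450, averaged 1.01 ± 1.05 CPM in females and 4972 ± 225 CPM in males (SD, n = 6), a log2 fold of −12.26 ± 0.61. Cyp2c13 (0.485 against 1664 CPM) and Cyp3a2 (3.38 ± 1.14 against 1734 ± 211 CPM) were likewise male-biased. Cyp2c12, the female-specific counterpart under growth hormone control, averaged 7551 ± 878 against 79.5 ± 39.2 CPM (6.57 ± 0.32), and Sult2a1, a hydroxysteroid sulfotransferase, 3592 ± 633 against 617 ± 215 CPM (2.54 ± 0.26). A1bg averaged 2231 ± 812 against 0.183 ± 0.330 CPM.

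The sex chromosome genes matched the labels. Xist averaged 949 ± 88.9 CPM in females and 5.79 ± 0.790 CPM in males. Ddx3y and Eif2s3y, both Y-linked, had 0 counts in sham females, at least 1075-fold and 576-fold lower than in males at a floor of 3 counts over the group. Other genes with the smallest p were Plaat3 (2.76 ± 0.13), Ces2e (2.78 ± 0.14) and Rasl10b (4.39 ± 0.23) on the female side. On the male side were the organic anion transporter Slc22a8 (1 count in females, 15358 in males, a ratio of 16593 with a 95% counting interval of 2978 to 655435), Ust5r (5 counts against 10281) and Hsd3b5 (0.381 against 1582 CPM).

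By edgeR 2139 of 10535 genes passed, 1126 higher and 1013 lower in females. All 16 measured male-biased liver genes of the fixed list were lower in females when adjusted over the list alone, 14 over all genes tested. Of 16 female-biased genes, 13 were higher and 2 lower by either count. Both lists passed camera (adjusted p = 5.55e-31 and 1.89e-17) and held with an estimated correlation (adjusted p = 3.72e-06 and 8.63e-06). Sex coincided with the count table and with the age at the start of exposure, so these cannot be told apart from it.

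Most genes of lipid synthesis had higher values in sham females. Of 24 cholesterol synthesis genes, 22 were higher when adjusted over the list alone and 17 over all genes, with a median log2 fold of 0.71 (camera adjusted p = 9.45e-11, and adjusted p = 0.205 with an estimated correlation). Examples are Fdps (1.91 ± 0.21) and Tm7sf2 (1.70 ± 0.12). Fatty acid and triglyceride synthesis genes were higher (14 higher and 1 lower over the list alone, 12 and 1 over all genes, median 0.78, adjusted p = 4.05e-07), with Elovl6 at 3.30 ± 0.41, as were PPAR alpha targets (20 higher and 3 lower over the list alone, 13 and 3 over all genes, adjusted p = 5.49e-07). With an estimated correlation the latter lists had adjusted p of 0.130 and 0.205. Kupffer cell and macrophage markers were higher (11 over the list alone, 9 over all genes, median 0.38, adjusted p = 1.3e-04, and adjusted p = 0.145 with an estimated correlation), with C1qa at 0.44 ± 0.08 and Vsig4 at 0.59 ± 0.13. In total 12 lists passed by camera, 2 with an estimated correlation and 20 by fry.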

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

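The tests of exposure and of the library axis as whole causes, the test of time of day, the library axis itself and the fits that use it or leave out animals 13 to 16 were chosen only after the result was seen.

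The first pattern is the library axis shared by consecutively numbered animals. Depth does not account for it, since thinning every library to the smallest total left the correlation between consecutive animals at 0.914. A bias by the genomic span of genes is argued against as the whole source, because 68.0% of the score variance was kept once the span trend was removed. The gene weights did follow span, with Spearman correlations of 0.387 in females and 0.231 in males. Span may therefore account for part of the axis. Of the 12 exposed libraries, 8 lay within the range of the sham scores. The axis was built with group means removed, so this overlap cannot test PCB 52 exposure as the whole cause. The scores do show that sham animals, which were not exposed, also spread along the axis, from −7.12 to 6.98. An order of collection or of library preparation shared by neighbouring animals may lie behind the axis. The labels record none, and GC content was not tested. Sham animals were numbered 1 to 12 and PCB 52 animals 13 to 24. An effect of order between these groups therefore cannot be told apart from exposure.

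The second pattern is the relation of female and male fold changes across genes. When animals were split at random with consecutive animals kept together, 5 of 100 splits, the real one included, gave a correlation as high as the real one. This was just at the limit of 5 set beforehand. The real value was 0.344 on log2 CPM differences and the highest other 0.440, so a structure shared by consecutive animals could produce this correlation. With the sexes split independently, 1 of 100 reached it, the real one (highest other 0.255). With consecutive animals kept together and the axis score removed, 1 of 100 splits did, the real one (0.199, highest other 0.182). The margin was narrow, and the axis weights were built with the real group means removed, which favours the real split here. This comparison therefore cannot tell whether the smaller correlation goes beyond structure shared by consecutive animals. Exposure and structure of another kind are not separated by the design.

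The third pattern is the female shift of fatty acid synthesis genes upward and of fasting, glucocorticoid responsive and immediate early genes downward. The library axis is argued against as the whole cause: with the score as covariate 4 of the 4 lists passed camera in the same direction, and their median log2 folds went from 0.39, −0.27, −0.52 and −0.39 to 0.38, −0.29, −0.48 and −0.41. Within groups their members followed the score little, with median r of 0.129, −0.057, −0.053 and 0.004. Camera also passed lists in random splits, so this point rests on the folds. The covariate removes only what follows this score, so other structure shared by animals was not tested. By fry the lists passed went from 4 to 1 with the covariate and to 0 without animals 13 to 16; the folds were not much smaller, while the median SE of members rose with the covariate from 0.160, 0.211, 0.253 and 0.221 to 0.179, 0.239, 0.285 and 0.263. With an estimated correlation 0 passed even without it. Time of day at collection is open too: 6 of 8 clock genes had 95% intervals in females that exclude a 2-fold change, but Bmal1 (−1.34 to 0.14) and Npas2 (−1.14 to 0.32) did not, and that of Per3 (0.02 to 0.58) excluded no change. Feeding and handling before collection, neither given in the labels nor tested, and exposure itself could also shift these genes.

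Random splits bear on the counts of genes and lists. In females 3 of 100 splits, the real one included, gave as many genes at an unadjusted p under 0.05 (1021 real, 1821 highest other). For the lists passed it was also 3 of 100 (12 real, 13 highest other). Other splits reached more, and the split counts were not adjusted for their number, so chance is less likely but not excluded. The female gene count was not stable, at 491 with 1 surrogate variable, below the 513 given by chance, and 625 without animals 13 to 16. In males chance is not excluded for either (20 of 100, 585 real, 1858 highest other, and 65 of 100, 3 real, 10 highest other). For the difference between the sexes it is not excluded either (96 of 100, 239 real, 1423 highest other, and 14 of 100, 8 real, 11 highest other). For the average over both sexes 2 of 100 splits gave as many genes (1625 real, 2681 highest other) and 8 of 100 as many lists (8 real, 10 highest other). With consecutive animals kept together it was 8 of 100 for genes (3163 the highest other) and 12 of 100 for lists (11 the highest other). Chance is therefore not excluded for either on average.

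With 0 genes called in females, in males, for the difference and on average, all 100 of 100 splits gave as many, and the highest others were 4, 144, 2 and 717. Keeping consecutive animals together, again 100 of 100 gave as many on average and the highest other was 1586. Splits that call many genes where the real count is 0 point to a structure of the samples. Across splits, the gap in axis score between the 2 sides of a split went with the number of genes at an unadjusted p under 0.05, with Spearman correlations of 0.622 in females, 0.668 in males and 0.847 with consecutive animals kept together. For sham females against sham males chance is excluded (1 of 100, 2139 real, 360 highest other).

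Of 192 sets of 6 values tested, 18 had a library standing apart from the other 5 of its group, where about 9.6 would by chance (1 in 20). In PCB 52 female replicate 1, Cyp2b1 was at 5.70 CPM (others 0.128 to 1.57) and Cyp2b2 at 86.5 CPM (others 1.21 to 14.3). In PCB 52 female replicate 4, Hamp was at 720.4 CPM (others 396 to 467), Tpst2 at 37.0 CPM (others 24.4 to 28.0) and Camlg at 6.16 CPM (others 8.05 to 9.10). In PCB 52 male replicate 5, Tpst2 was at 31.2 CPM (others 22.6 to 25.04) and Gadd45b at 4.86 CPM (others 2.21 to 3.18). In PCB 52 male replicate 3, C1h19orf47 was at 9.36 CPM (others 6.93 to 7.63) and Mcm7 at 10.7 CPM (others 12.46 to 13.02). PCB 52 male replicate 1 had Nqo1 at 10.8 CPM (others 7.76 to 8.86) and replicate 2 had Uggt1 at 156 CPM (others 116 to 127).

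In sham males, A1bg was at 0.844 CPM in replicate 6 (others 0 to 0.1304), Dstyk at 7.57 CPM in replicate 3 (others 8.39 to 8.86) and Slc22a8 at 260.9 CPM in replicate 4 (others 329 to 357). In sham females, Slc22a8 was at 0.125 CPM in replicate 5 (others 0), Alb took 13.3% of the counts in replicate 4 (others 9.18 to 10.6%) and replicate 6 had an axis score of 5.30 (others −5.58 to −1.50).

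The responses of females and males differed by camera in 8 lists, with adjusted p of 0.0391 for Nrf2 targets and for cholesterol synthesis, 0.00485 for fatty acid and triglyceride synthesis, 7.71e-04 for cell cycle, 0.0222 for gluconeogenesis and fasting, 3.19e-04 for glucocorticoid responsive, 0.00147 for stellate cell and collagen and 0.0231 for ribosomal protein genes. None of the 8 passed with an estimated correlation, where the smallest adjusted p was 0.0927, or by fry.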

How the results depend on the processing

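The axis covariate, the fit without animals 13 to 16 and the block for consecutive animals were chosen only after the result was seen; the other settings were planned. No named gene past the threshold changed direction under a setting, and no list did while it still passed. A list that changed direction and no longer passed was counted as having lost its call. In the comparisons of exposure no gene passed in the main fit, so no gene there had a call to lose. Of the values for single genes and lists, 8426 kept their direction and side of the threshold, 145 lost and 47 gained a call and 121, all of genes that did not pass, changed sign. Among these, Cyp2b2 in females went from 0.45 to −0.86 without PCB 52 replicate 1, and Cyp3a23-3a1 in males, at 0.02, took the other sign without sham replicates 3 or 6 or PCB 52 replicate 5. Where counts differed, the cause was not tested. In females, against 0 genes by edgeR, DESeq2 called 27, limma-voom with quality weights 1 and the fit of all 24 libraries 1; leaving out 1 library gave 0 to 8 (1 without sham replicate 5, 8 without PCB 52 replicate 4). In males, against 0, DESeq2 called 1 and leaving out 1 library gave 0 to 0. On average over both sexes, against 0, DESeq2 called 99, limma-voom 7 and an adjusted p threshold of 0.10 gave 22; leaving out 1 library gave 0 to 15 (2 without sham female replicate 6, 1 without PCB 52 female replicate 3, 15 without PCB 52 female replicate 4). For the difference between the sexes leaving out 1 library gave 0 to 0, and for the sham contrast 1928 to 2189.

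Lists passed by camera were fewer with an estimated correlation, at 0 in females, 0 in males, 0 for the difference and 0 on average, and by fry at 6, 0, 0 and 5. Leaving out 1 library gave 6 to 12 lists in females (6 without sham replicate 5), 1 to 6 in males (1 without PCB 52 replicate 2, not among the 3, and 6 without PCB 52 replicate 5), 4 to 11 for the difference and 7 to 10 on average. For the difference, 4 passed without sham male replicate 4, and 5 without sham female replicate 2, sham male replicates 5 or 6, or PCB 52 male replicates 4 or 5. Without animals 13 to 16, 1 list passed in males, not among the 3 given above, and 13 in females, 9 of them shared. With the axis covariate, 11 passed in females (9 shared), 3 in males (2 shared), 6 for the difference and 10 on average (8 shared), while fry passed 2 in females, 0 in males, 0 for the difference and 0 on average. Without animals 13 to 16 fry passed 0 lists in all 4 comparisons.

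With the axis covariate edgeR again called 0 genes in females, in males, for the difference and on average, with 608, 397, 315 and 869 at an unadjusted p under 0.05. With 1 surrogate variable these were 491, 512, 340 and 827, against 1021, 585, 239 and 1625. Without animals 13 to 16 they were 625 in females, 408 in males and 851 on average. The 10 named genes of each of these comparisons kept their sign with the axis covariate, with 1 surrogate variable and without animals 13 to 16. A kept sign is a weak check here, since these genes were chosen by smallest p. The smallest share of a log2 fold kept was 0.491 in females, with 1 surrogate variable, and 0.585 in males, without animals 13 to 16. Akr1c13 in females went from 0.52 to 0.33 and Uso1 on average from 0.28 to 0.19, while Acly in females stayed at 0.66. The block for consecutive animals called 0 genes for the difference (355 unadjusted) and 0 on average (1284), and 2467 in the sham contrast. Females correlated best with the consecutively numbered male in 5 of 12 cases, a hint from the data and not the design. Depth limited Cyp2b1 and other genes near 1 CPM in females.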

Other observations

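The fits with the library axis score as covariate in this part were chosen only after the result was seen.

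In the list of unfolded protein and integrated stress response genes, 2 of 20 members were higher on average over the sexes when adjusted over the list alone, against 0 over all genes by edgeR. These were Hsp90b1 (log2 fold 0.24 ± 0.07), an endoplasmic reticulum chaperone, and Hyou1 (0.28 ± 0.08), another. The list as a whole did not pass (11 above and 9 below 0, median 0.07, camera adjusted p = 0.541), and Chac1 (−0.78 ± 0.29) went the other way. In the heat shock list, Hspe1, a mitochondrial chaperonin gene, was the 1 member to pass over the list alone (−0.31 ± 0.08), and that list had an adjusted p of 0.737. With the axis score as covariate Uso1 stood at 0.19 on average, so part of its value may follow the axis.

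A pair of MHC class II genes had counts in some libraries and nearly none in others, and both were chosen after their values were seen. Whether those animals lacked the transcripts, or their reads were not assigned to these genes, was not tested. RT1-Bb had 0 counts in 9 libraries and 5.68 to 18.1 CPM in the other 15. RT1-Ba lay at 0.217 to 1.10 CPM in those same 9 libraries and at 7.61 to 24.6 CPM in the 15. The 9 libraries were 3 sham females, 3 PCB 52 females, 0 sham males and 3 PCB 52 males.

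Sult2a2, a female-biased hydroxysteroid sulfotransferase, was at 8.22 CPM in sham female replicate 1 and at 533 to 1706 CPM in the other 11 females, while males stayed at 2.61 CPM or less. Lcn2, an acute phase gene, was at 33.3 CPM in PCB 52 male replicate 1 and averaged 0.942 CPM in sham males. These genes were also chosen after their values were seen.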
